A study of Mus musculus with 4 samples.

How the data were processed

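Single cells of 4 mouse libraries were read from the files as deposited, a vehicle and a 1NMPP1 library of the growth plate region and such a pair of lumbar dorsal root ganglia (DRG). The labels place 1 library in each group and do not say how many animals it holds. Per the labels' protocols, the end of the femur with the injured growth plate was digested 5 times with collagenase, ganglia were digested with papain and then with collagenase and dispase, and DMSO vehicle was given to the controls. The authors deposited raw UMI counts per gene and cell barcode, made with Cell Ranger 7.2.0 per the file headers and with mm10 as genome per the submitters' processing notes. The kit chemistry and the annotation release used for counting are not given in the sources used here. No normalization had been applied to the counts, whose values are whole numbers, and no barcode held fewer than 500 UMIs. The feature tables list the same 32285 genes. The vehicle growth plate table has an added sequence named AAV_PHP_S, both DRG tables have tdTomato, and the 1NMPP1 growth plate table has none.

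Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept. The gene minimum left out 80, 65, 393 and 355 barcodes of the vehicle growth plate, 1NMPP1 growth plate, vehicle DRG and 1NMPP1 DRG libraries, and the mitochondrial limit 152, 135, 583 and 75. Doublets were scored with Scrublet in each library, and the cells with the highest scores were removed at 0.8% per 1000 barcodes, which took 731, 1115, 108 and 55 barcodes; the threshold that Scrublet sets itself would have marked 258, 683, 26 and 3. This left 8660, 10532, 2843 and 2151 cells.

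Both libraries of a tissue were clustered together on 2000 variable genes, 30 principal components and 20 nearest neighbours with the Leiden method at resolution 1, and clusters of at least 60 cells were split further where another class scored at least 1 and at least 0.5 of the highest score. The software was Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A cluster was called X-like from 37 marker sets fixed beforehand. Its score for a class was the mean over markers of the log2 ratio of its CPM to the median over clusters, and a name needed a score of at least 1, at least 3 detected markers and more own markers than markers of any other class among the leading genes. The name is that of the highest-scoring class that met all conditions, which was not always the class with the highest score. The markers stood before the clusters were seen, but this scoring rule did not. It was settled afterwards and changed 3 times. Clusters left without a name held 1.81% and 1.07% of the kept growth plate cells and 2.71% and 1.30% of the kept DRG cells, vehicle first.

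UMIs were summed per library and class and scaled to CPM over all UMIs of that class. Shares carry exact Clopper-Pearson intervals, CPM exact Poisson intervals and ratios exact conditional intervals, all at 95%. With 1 library per group no test was run, no p-value is given and no changed genes are counted. Classes were read from 100 cells in both libraries, and sensory neuron-like cells from 50. These minimums left out chondrocyte-like and macrophage-like cells, so classes from 30 cells were added after the data were seen. The log2 ratio used 0.5 UMI added to each sum. Gene lists, 31 in number, were fixed before the data were examined, as were the classes in which each is read, the markers, the minimums and the rule for named genes. A list is described by the median log2 ratio of its members with at least 20 UMIs in the class, and by the percentile of that median among 10000 random lists of the same size and like expression in the same libraries. Where a member had 0 UMIs in a library (Mepe in chondrocyte-like cells, Ccl7 in satellite glia-like cells and Gpnmb in DRG macrophage-like cells), setting it at 3 UMIs keeps it on the same side of the median, which does not move.

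The genes named by the rule are the 3 with the highest and the 3 with the lowest log2 ratio in chondrocyte-, osteoblast-, fibroblast-, endothelial-, macrophage- and neutrophil-like cells of the growth plate and in sensory neuron-, satellite glia-, myelinating Schwann-, fibroblast-, endothelial- and macrophage-like cells of the DRG, where a class had enough cells. They had at least 100 UMIs in the class, a UMI in at least 10% of its cells in the library where they were higher, and a mean CPM of at least 25% of that in the highest class. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, predicted and sex-linked genes were left out. This gave 36 names in the classes planned and 54 with the added ones. Members of the lists could be named too, and in each list the examples given were chosen after their values were seen. Values of a few genes, the targeted one among them, are not reported here.

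A cell was called male with UMIs of Ddx3y, Eif2s3y, Kdm5d or Uty and none of Xist, and female the other way round. Cells with neither kind made up 31.1%, 32.5%, 31.6% and 33.0% of kept cells and cells with both 3.30%, 3.50%, 2.78% and 2.05%, in the order of libraries above. Positions and transcript sequences are from GENCODE mouse release 21 on GRCm38, the assembly that mm10 names. A gene counted as sharing sequence where at least 20% of the 50-base stretches, taken every 10 bases over the last 500 bases of its longest transcript, occur in a transcript of another gene. The median log2 ratio of all measured genes departed from 0 by over 0.1 in further classes, at -0.24 in growth plate erythroid-like cells and at 0.12, -0.44 and 0.11 in DRG B cell-, erythroid- and neutrophil-like cells.

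The steps were tested on simulated counts drawn from the means of growth plate neutrophil-like and DRG satellite glia-like cells, with 200 genes changed. Of the genes changed by a fold of 0.25, 0.5, 2 and 4, a log2 ratio within 0.5 of the truth was found for 94%, 98%, 98% and 100% among 13361 genes of the neutrophil-like cells and for 88%, 92%, 100% and 100% among 12648 genes of the satellite glia-like cells. The intervals held the truth for 95.4% and 95.9% of genes. The counts were drawn as Poisson values without spread between cells or libraries, so coverage near 95% was set in advance. It says nothing about counts that vary more than this. Of 200 unchanged lists of 16 members, 5% and 2.5% lay outside the central 95% of random lists, and 100% of lists changed by 0.5 lay above it, among 13362 and 12662 genes. Members were picked at random, so lists of genes that vary together were not simulated.

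The alternatives set beforehand were no doublet removal, a minimum of 500 genes, a limit of 10% mitochondrial UMIs, resolutions of 0.5 and 2, clustering of each library on its own, shares of cells that are not blood, median-of-ratios scaling, totals without mitochondrial, ribosomal and hemoglobin genes, thinning to 1000 UMIs per cell for genes, the mean over cells of each cell's CPM, 5 UMI added, list members from 100 UMIs, list means, and named genes from 30 UMIs. Male-called cells alone, female-called cells alone, thinning for lists, the peptidergic-like neuron clusters alone, the largest cluster alone of DRG satellite glia-like, myelinating Schwann-like and B cell-like and of growth plate neutrophil-like and monocyte-like cells, DRG endothelial-like cells without UMIs of mural markers, and classes from 30 cells were chosen after seeing the data. The clusters called peptidergic-like are 21.0, 21.1 and 21.2, although the best score of 21.1 was not for peptidergic markers.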

Results

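Single-cell RNA was counted in 4 libraries from mice in which a receptor kinase of sensory neurons carries a change that lets the compound 1NMPP1 inhibit it. The physis, or growth plate, had been injured, and tissue was taken 7 days later. A vehicle library and a 1NMPP1 library came from the end of the femur around the injured growth plate, and another such pair from lumbar dorsal root ganglia (DRG), which hold the cell bodies of the sensory neurons. The 1NMPP1 animals were injected 48 h and 2 h before surgery at 17 µg/g and then drank water with 40 µM of the compound. Each group has 1 library, so no difference below has a replicate check, no p-value is given, and the number of animals per library is not given in the sources used here. The growth plate libraries held 102693014 UMIs in 9560 barcodes (vehicle) and 139703885 UMIs in 11807 barcodes (1NMPP1). The DRG libraries held 57303894 UMIs in 3675 barcodes and 32791945 UMIs in 2612 barcodes. After filtering, 8660, 10532, 2843 and 2151 cells were kept in that order, with medians of 6496.5, 7069, 10427 and 7026 UMIs. All intervals are 95% and cover counting error only, and log2 ratios are 1NMPP1 over vehicle.

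The libraries differed in the sex of their cells. Cells with Y-linked UMIs and no Xist made up 49.7% of the vehicle and 24.9% of the 1NMPP1 growth plate cells, and cells with Xist and no Y-linked UMIs made up 15.9% and 39.1%. In the DRG the male-called shares were 45.5% and 17.4%, and the female-called shares 20.1% and 47.6%. Cells of both calls were thus present in every library, in proportions that differed between vehicle and 1NMPP1.

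In the growth plate, chondrocyte-like cells were scarcer in the 1NMPP1 library. They made up 1.34% of kept vehicle cells (116 cells, 1.11% to 1.60%) and 0.370% of kept 1NMPP1 cells (39 cells, 0.263% to 0.506%), a log2 ratio of -1.84 (-2.42 to -1.32). Marrow dominated both libraries, with blood cell classes at 96.4% and 98.1% of kept cells. Among the 154 and 86 cells that were not blood, chondrocyte-like cells were 75.3% (67.7% to 81.9%) and 45.3% (34.6% to 56.5%), fibroblast-like cells 12.3% and 36.0%, and endothelial-like cells 12.3% and 18.6%. The fibroblast-like cells are a single cluster of 19 and 31 cells led by Col1a1, Bglap, Col1a2 and Postn, which scored higher as marrow stromal (5.42) and as osteoblast cells (5.13) and took its name from the markers that led it. Neutrophil-like cells were 50.5% (49.4% to 51.5%) and 53.6% (52.6% to 54.5%) of kept cells, B cell-like cells 22.0% and 21.6%, monocyte-like cells 8.65% and 9.77%, granulocyte progenitor-like cells 6.41% and 5.12%, and erythroid-like cells 2.84% and 2.04%. The chondrocyte-like log2 ratio was -1.08, from 68 and 39 cells, when each library was clustered on its own, and -0.72 among cells that were not blood. It was -2.57 within male-called cells (82 and 8 cells) and -1.44 within female-called cells (19 and 21 cells). Cells of clusters left without a name were 1.81% and 1.07%.

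**Figure D1:**
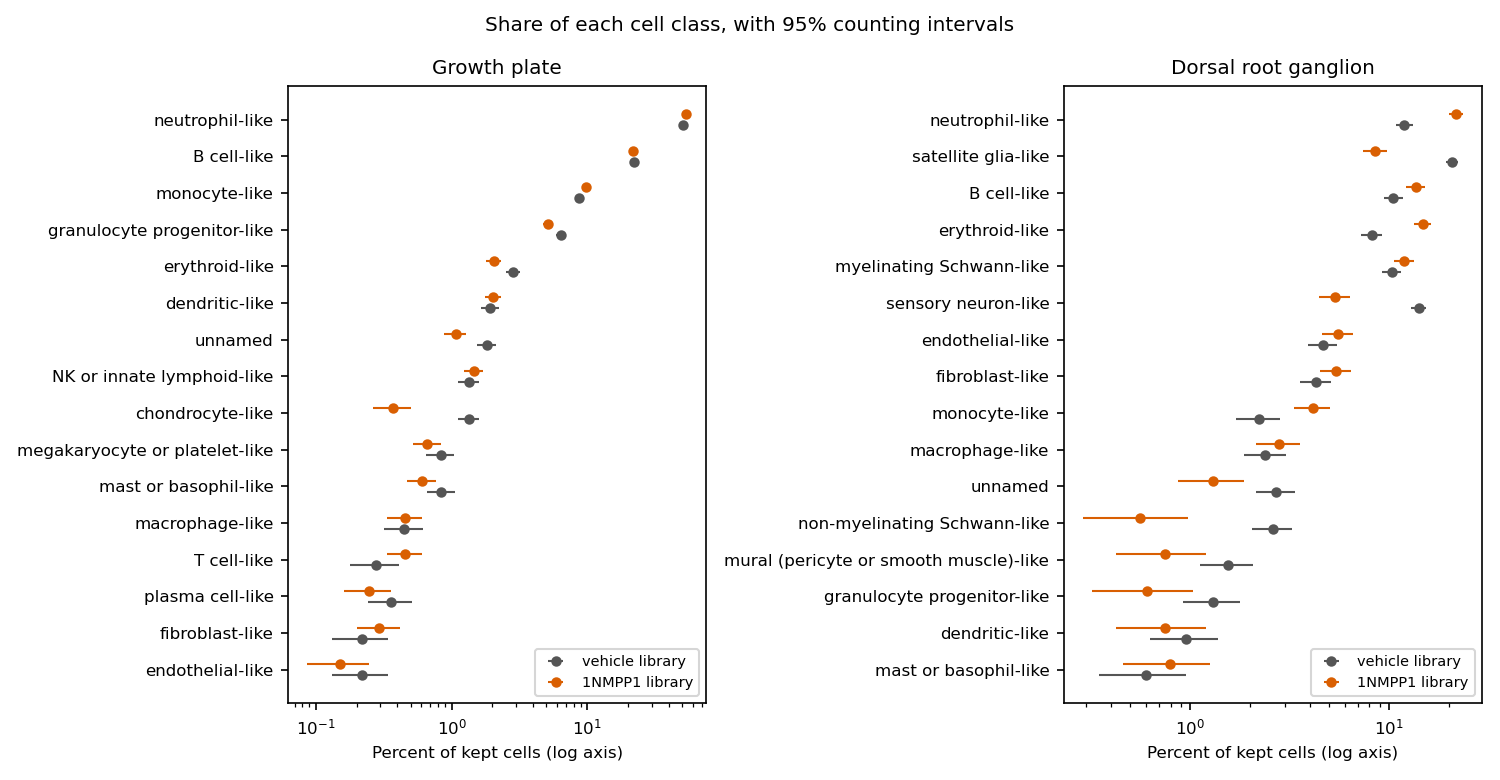
Share of kept cells in each class, in percent on a log axis, for the vehicle (grey) and 1NMPP1 (orange) libraries of each tissue; bars are 95% exact binomial intervals that cover counting error only, and classes with at least 30 cells over both libraries are drawn. Chondrocyte-like cells stand at 1.34% and 0.370% in the growth plate, and satellite glia-like cells at 20.8% and 8.55% in the ganglia.

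Growth plate neutrophil-like cells had higher interferon response genes in the 1NMPP1 library. All 14 measured members were higher, with a median log2 ratio of 0.73 that stood at percentile 100 among 10000 random lists of like expression. Ifit3, an interferon-induced antiviral gene, was at 4.39 CPM in vehicle and 11.8 CPM in 1NMPP1 cells, a log2 ratio of 1.43 (1.16 to 1.71). Usp18, which restrains interferon signalling, was higher by 1.23, Xaf1 by 1.05, Oasl2 by 0.87, the regulator Irf7 by 0.68 and Isg15 by 0.58. Cells lay in different clusters by library, with 40 vehicle and 150 1NMPP1 cells in a neutrophil-like cluster with Slfn4 among its leading genes (log2 ratio of shares 1.61), 44 and 107 in another with Ifit1 and Slfn4 (0.99), and 25 and 70 in a monocyte-like cluster with Ifit3 and Cxcl10 (1.18). Within the largest cluster of the class alone the median was 0.47 in neutrophil-like cells, where Isg15 turned to -0.18, and 0.27 in monocyte-like cells. The list was also higher in monocyte-like cells (median 0.55, 15 of 15 members, with Ifit2 at 1.07 and Ifit3 and Usp18 at 0.75) and in B cell-like cells (median 0.45, 15 of 15 members, with Ifi44 at 1.58 and Ifit3 at 1.78 from 8 and 43 UMIs). In neutrophil-like cells the median was 1.13 within male-called and 0.44 within female-called cells. In B cell-like cells it was 1.09 within male-called cells and turned to -0.12 within female-called cells, where Ifit1 was at -0.06 and Ifit3 at -0.17.

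Immediate early and dissociation stress genes were higher in the same neutrophil-like cells, with a median of 0.25 (14 of 16 members, percentile 100). Jund was at 0.61, Atf3 at 0.55 and Zfp36 at 0.42. Of 15 inflammatory genes 11 were higher (median 0.14, percentile 97.9), among them the chemokine Ccl3 at 0.53. Neutrophil granule genes had a median of 0.01 (percentile 30.8), with Camp at -0.13, Ltf at -0.07 and Mmp8 at -0.03, but within the largest cluster alone the median was -0.17, Ltf was at -1.87, Camp at -1.32 and Mmp8 at -0.26. The median of proliferation genes was -0.07 (12 of 18 members lower, percentile 0.06) and that of hypoxia and glycolysis genes -0.03. The proliferation median turned to 0.20 within female-called cells and to 0.33 within the largest cluster, where the inflammatory median was -0.0452. By the fixed rule of size, the genes named in neutrophil-like cells were Hist1h2ap at 3.39, Eno1 at 2.10 and Oas1a at 1.57 on the high side, and Prok2, a secreted chemoattractant, at -1.0, Eno1b at -1.0 and Plscr2 at -0.46 on the low side. Of these, Hist1h2ap shares 93.2% of its searched transcript end with another gene, Eno1 73.9%, Eno1b 82.6% and Oas1a 58.7%, so their values are uncertain.

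In growth plate monocyte-like cells the medians of the other lists were 0.12 for immediate early genes, 0.07 for proliferation genes, 0.07 for inflammatory genes (with Cxcl1 at 0.90 and Il1a at 0.76), 0.04 for alternatively activated macrophage genes, -0.11 for hypoxia genes and -0.17 for osteoclast genes. Within the largest cluster the inflammatory median was -0.0616, the immediate early median -0.0082, Cxcl1 was at -0.78 and Il1a at -0.11. In granulocyte progenitor-like cells 11 of 16 immediate early genes were lower (median -0.11, percentile 0.27), with the heat shock genes Hspa1a at -1.32 and Hspa1b at -1.22. The granule enzyme genes Elane and Mpo were at 0.21 and 0.18 and the granule list at -0.04. The immediate early median turned to 0.05 within female-called cells. Hspa1b was at 0.03 after thinning to 1000 UMIs and at 0.12 within male-called cells.

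Chondrocyte-like cells were read after the data were seen, since their 39 cells in the 1NMPP1 library missed the minimum of 100 set beforehand. Cartilage matrix genes had a median of 0.11 (14 of 17 members higher, percentile 87.6), with Col2a1, the main cartilage collagen, at 0.04 and the proteoglycan Acan at 0.13. Hypertrophic chondrocyte genes had a median of 0.05 (percentile 76.9), with Col10a1 at 0.37 and the hedgehog ligand Ihh at -0.20. Within female-called cells Col10a1 was at -0.84. FGF ligands and receptors were lower (median -0.70, 5 of 6 members, percentile 0.01), with Fgf18 at -2.86 from 35 and 2 UMIs (-6.26 to -1.20), Fgfr1 at -1.20, Fgfr2 at -0.83 and Fgfr3 at 0.27. FGF and ERK feedback genes had a median of -0.36 (percentile 1.52), with Etv5 at -0.91 and Spred1 at -0.56. All 5 measured osteoclast coupling genes were lower (median -1.92), on few UMIs, with 36 and 2 for Il34, 22 and 1 for Kitl, 18 and 2 for Vcam1 and 27 and 6 for Csf1. With no cells removed as doublets Kitl was at 1.27, Vcam1 at 0.86, Etv5 at 0.38 and Fgfr1 at 0.19.

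Fibrous matrix genes were lower in the same chondrocyte-like cells (median -0.43, 16 of 21 members, percentile 0), with Col1a1 at -6.39 (-6.93 to -5.94), Col3a1 at -2.96, Col1a2 at -2.22, and with Postn at -3.63 (-7.01 to -2.02) from 2 UMIs and Tnc left with 1 UMI in the 1NMPP1 library. Osteogenic genes had a median of -0.21 (percentile 1.12), with the bone matrix genes Ibsp at -1.48 and Spp1 at -1.19. With no cells removed as doublets the fibrous matrix median was 0.08, Col1a1 was at 0.38 and Spp1 at 3.54, and with cells kept from 500 genes Col1a1 was at 0.26. The class also took different parts from the libraries, with 56 of the vehicle cells but 13 of the 1NMPP1 cells in a cluster led by Prg4 and Chad, against 35 and 14 in cluster 19.2 and 25 and 12 in cluster 19.3. Proliferation genes had a median of 0.28 (percentile 99.9), with Mcm3 at 1.89, Mcm5 at 1.44 and Ccnb2 at -1.50, and the median turned to -0.09 with members from 100 UMIs and to -0.10 within female-called cells. The medians of the remaining lists were -0.20 for hedgehog signalling, 0.11 for Wnt signalling, 0.0048 for BMP and TGF-beta signalling, -0.31 for angiogenesis, 0.10 for neurotrophins and axon guidance, 0.09 for immediate early genes and -0.06 for hypoxia and glycolysis, all within the central 95% of random lists. The genes named by the rule were Eno1 at 2.36, Stk32b at 2.12 and Fam155a at 1.37, and Itgbl1 at -6.31 (-12.20 to -4.40), Spon1 at -5.09 (-7.60 to -3.75) and Igfbp6 at -2.87; Fam155a was at -2.15 after thinning.

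Growth plate macrophage-like cells, 39 and 48 cells also read after the data were seen, had higher alternatively activated macrophage genes in the 1NMPP1 library. Of 10 such genes 8 were higher (median 0.84, percentile 100), with Gpnmb at 1.71, Trem2 at 0.78 and Cd163 at 1.34 from 7 and 18 UMIs. Cd163 was at -0.26 after thinning to 1000 UMIs and at -1.46 when each cell weighed alike. The genes named by the rule were Spp1 at 2.95, Gpnmb at 1.71 and the lysosomal protease Ctsl at 1.63, and on the low side the chemokines Cxcl1 at -4.15 and Cxcl10 at -2.08 and the adaptor Traf3 at -2.05. Inflammatory genes had a median of -0.40 (10 of 15 members lower), although Il1b was at 1.91. Proliferation genes had a median of -0.57, with Top2a at -2.05, and immediate early genes of -0.37. The interferon (0.23), osteoclast (-0.08), antigen presentation (0.17), FGF feedback (-0.13) and hypoxia (0.02) medians lay within the central 95% of random lists. Of the 2 clusters of this class, 22.0 held 24 vehicle and 22 1NMPP1 cells and 22.1, which is led by Mmp12 and has a median of 1121 UMIs, held 15 and 26.

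In the DRG, satellite glia-like cells and the sensory neuron-like cells of the shallow clusters 9 and 13 were scarcer in the 1NMPP1 library and blood cells more frequent. Satellite glia-like cells, which wrap the neuron cell bodies, made up 20.8% of kept vehicle cells (592 cells, 19.3% to 22.4%) and 8.55% of kept 1NMPP1 cells (184 cells, 7.41% to 9.82%), a log2 ratio of -1.28. Sensory neuron-like cells made up 14.1% (402 cells, 12.9% to 15.5%) and 5.35% (115 cells, 4.43% to 6.38%), a log2 ratio of -1.40. The difference lay in clusters 9 and 13, whose median depths were 979.5 and 730 UMIs and which held 319 and 61 neurons (11.2% and 2.84% of kept cells, log2 ratio -1.97). The deeper neuron clusters held 83 and 54 cells (2.92% and 2.51%), a log2 ratio of -0.21 (-0.74 to 0.29). Non-myelinating Schwann-like cells were 2.60% and 0.558%, a log2 ratio of -2.17 (-3.24 to -1.33) from 74 and 12 cells. Blood cell classes together were 38.8% and 60.6%, with neutrophil-like cells at 12.0% and 21.9%, erythroid-like cells at 8.23% and 14.8%, B cell-like cells at 10.6% and 13.7% and monocyte-like cells at 2.22% and 4.14%. Granulocyte progenitor-like cells, also counted as blood, were 1.30% and 0.604% (37 and 13 cells). Whether the blood cells came from the ganglia or from tissue carried along was not tested. Among the 1662 and 820 cells that were not blood, satellite glia-like cells were 35.6% and 22.4%, sensory neuron-like cells 24.2% and 14.0%, myelinating Schwann-like cells 17.7% and 31.3%, endothelial-like cells 8.0% and 14.5% and fibroblast-like cells 7.34% and 14.3%. The neuron shares among these cells include clusters 9 and 13, so they do not speak for the deeper neurons. The mitochondrial limit removed 15.9% of vehicle and 2.87% of 1NMPP1 barcodes, a gap that can shift the DRG shares. With a limit of 10%, 29 of the shares of both tissues stayed within their counting intervals and 1 moved. The sensory neuron-like log2 ratio turned to 0.39 within male-called cells (64 and 24 neurons) and to 0.14 within female-called cells (15 and 30 neurons), which leave out the neurons without a sex call.

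Summed over sensory neuron-like cells, transcripts of non-peptidergic nociceptor genes were more frequent in the 1NMPP1 library before thinning. Cluster 9, whose best score was for such markers, nonetheless held a smaller share of its neurons. Values of single genes depended on how cells were weighed. The non-peptidergic list had a median of 0.55 (7 of 11 members higher, percentile 99.9), with the itch-related Nppb at 2.95 and Mrgpra3 at 2.52, Gfra2 at 1.24 and Mrgprd at -0.26. General nociceptor genes had a median of -0.17 (11 of 16 members lower, percentile 2.27). Calca, the gene of the neuropeptide CGRP, was at -0.68, Tac1, the gene of substance P, at -0.82, Bdnf at -0.82 and the heat-gated channel Trpv1 at -0.40, while the sodium channel genes Scn10a and Scn11a were at 0.51 and 0.55. When each neuron weighed alike Calca was at 0.19 and Trpv1 at 0.355, and after thinning Bdnf was at 0.0769 and Scn11a at -0.43. A-fibre genes had a median of -0.25 (percentile 0.49), with Nefh at -0.56, Kcnc1 at -0.72 and Runx3 at -1.11. Interferon response genes were lower (median -0.49, 10 of 13 members, percentile 0.02), with Isg15 at -2.54 and Bst2 at -0.68. Of 17 axon injury genes 15 were lower, by little (median -0.19, percentile 5.23), with Atf3 at -0.17, Gap43 at -0.15, Gal at -0.19 and Sprr1a at -1.23.

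The neurons behind these values differed between the libraries, with median depths of 1041.5 UMIs in vehicle and 19716 UMIs in 1NMPP1 cells. Clusters 9 and 13, with medians of 1005 and 671 UMIs in the vehicle library, held 47.3% and 32.1% of vehicle but 24.3% and 28.7% of 1NMPP1 neurons. The best score of cluster 9 was for non-peptidergic markers (2.25) and that of cluster 13 for A-fibre markers (3.85). Cluster 25, with a median of 128678 UMIs in the vehicle library, held 6.47% and 19.1%. Its best score was for C-low-threshold mechanoreceptor markers (5.15). Within the peptidergic-like clusters alone the general nociceptor median was 0.03, the axon injury median 0.12 and the A-fibre median 0.31, and Gfra2 was at -1.05. After thinning to 1000 UMIs the non-peptidergic median was -0.48 and the general nociceptor median 0.04. Medians over the remaining lists were -0.18 for neuron secreted factors, 0.20 for cholesterol synthesis, 0.18 for FGF and ERK feedback, -0.01 for proliferation, -0.09 for immediate early and -0.07 for hypoxia genes. The rule named Shcbp1l at 3.38, Slamf1 at 3.35 and Adamts13 at 3.25, and Crtam at -2.08, the potassium channel subunit Kcnmb2 at -1.70 and Ndst4 at -1.68. Slamf1, Kcnmb2 and Ndst4 turned to -1.71, 0.34 and 0.21 when each neuron weighed alike, and Adamts13 took the other sign within male-called cells.

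DRG satellite glia-like cells had higher immediate early, ERK feedback and cholesterol synthesis genes in the 1NMPP1 library. The immediate early list had a median of 0.78 (14 of 16 members higher, percentile 100), with Fosb at 1.71 (1.66 to 1.76), Dusp1 at 1.70, Btg2 at 1.47, Egr1 at 1.33 and Fos at 0.76. FGF and ERK feedback genes had a median of 0.50 (11 of 13 members, percentile 99.6), with the ERK phosphatase Dusp6 at 1.79, Spry1 at 1.44 and Etv5 at 1.00. Cholesterol synthesis genes had a median of 0.36 (11 of 15 members, percentile 99.5), with Dhcr7 at 1.26, Lss at 1.23 and Hmgcs1 at 0.56. Named by the rule were Egr2 (chromosome 10, 67535475 to 67542188), a transcription factor of myelinating glia, at 2.59 (2.46 to 2.72), Aatk at 2.20 and Insyn2b at 2.17, and Hmox1 (chromosome 8, 75093621 to 75100589), the heme-degrading enzyme, at -2.87 (-3.11 to -2.65), Pou2f3 at -3.11 and C1qtnf9 at -4.16 (-10.06 to -2.23). Inflammatory genes were lower (median -0.50, 8 of 11 members, percentile 0.24), on few UMIs, with 38 and 0 for Ccl7, 27 and 1 for Il6 and 33 and 3 for Cxcl2. Satellite glia activation genes had a median of 0.18 (percentile 92.8), with Gfap at 0.28 and Apoe at 0.01. Proliferation genes had a median of -0.18, with Top2a at -2.20 and Ube2c at -2.76, and these turned to 2.75 and 1.96 within female-called cells. The medians of the interferon (-0.05), neurotrophin (0.05), hypoxia (0.08), myelin (0.14), Schwann repair (-0.07) and antigen presentation (-0.21) lists lay within the central 95% of random lists. The class took different parts from the libraries, with 349 and 139 cells in a cluster led by Bcan and Fabp7, 94 and 10 in a cluster led by Wfdc18, 98 and 2 in a cluster led by Bcan and Prss35, and 51 and 33 in the last. Within the first of these alone the immediate early median was 0.71, the FGF and ERK feedback median 0.44, the cholesterol synthesis median 0.38 and the inflammatory median -0.70. The median of all measured genes was 0.15 in this class, against which these values are to be read. Thinning turned the inflammatory median to 0.36 and the proliferation median to 0.28, but left only 4 measured members of each list.

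Myelinating Schwann-like cells had higher immediate early, cholesterol synthesis and myelin genes in the 1NMPP1 library. Their immediate early median was 0.74 (14 of 16 members, percentile 100), with Egr1 at 1.47 and Ier2 at 1.18, and their cholesterol synthesis median 0.46 (13 of 15 members, percentile 99.95), with Insig1 at 1.21, Lss at 1.22 and Dhcr7 at 1.19. Myelin genes had a median of 0.24 (11 of 12 members higher, percentile 99.7), with Prx at 0.91 and Pmp22 at 0.48. Mbp was at 0.19 and took the other sign after thinning (-0.10), and Dhcr7 was at -0.03 within female-called cells. The genes named were Rapgef3 at 1.79, Egr2 at 1.63 and Vps26c at 1.61, and Cdc42ep2 at -1.48, Fem1b at -1.26 and Nolc1 at -1.23. FGF and ERK feedback (0.14), Schwann repair (-0.22), neurotrophin (-0.27) and hypoxia (-0.08) medians lay within the central 95%, and the proliferation median was 0.62 from 5 members. The class took different parts from the libraries, with 213 and 229 cells in its largest cluster and, at median depths of 681 and 1088.5 UMIs, 38 and 9 cells in another and 34 and 8 in a further one. Within the largest cluster alone the medians were 0.73 for immediate early, 0.42 for cholesterol synthesis and 0.30 for myelin genes. The median of all genes was 0.10.

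**Figure D2:**
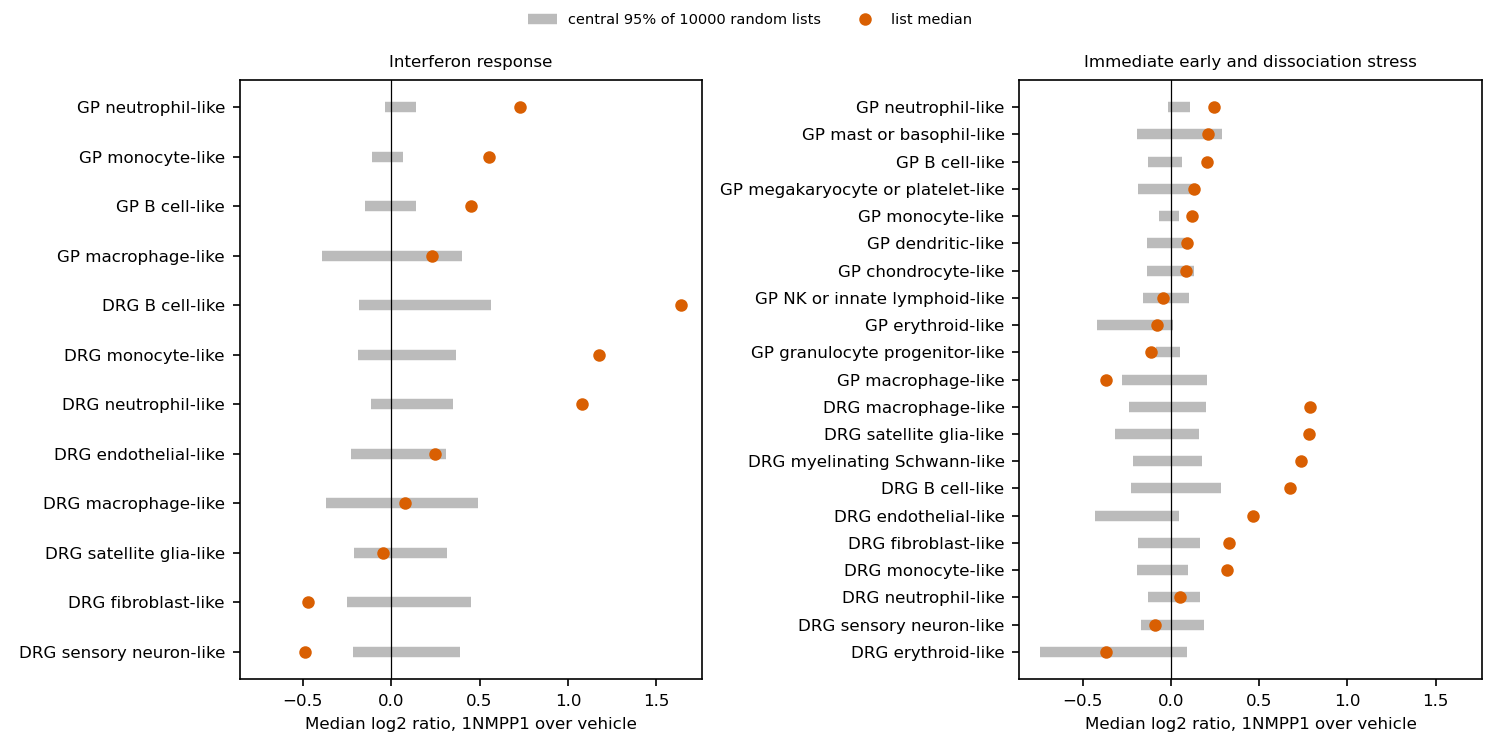
Median log2 ratio, 1NMPP1 over vehicle, of interferon response genes (left) and of immediate early and dissociation stress genes (right) in each class read; points are list medians and grey bars the central 95% of 10000 random lists of the same size and like expression. Interferon medians reach 0.73 in growth plate and 1.08 in DRG neutrophil-like cells but -0.49 in sensory neuron-like cells, and immediate early medians 0.78 in satellite glia-like cells.

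DRG endothelial-like cells, 133 and 119 cells with medians of 18773 and 8961 UMIs, had higher immediate early and dissociation stress genes in the 1NMPP1 library and lower medians of the inflammatory and the FGF and ERK feedback list, both of which turned after thinning. Rgs5, a mural cell marker looked up after the values were seen, held 549 UMIs in 19 vehicle cells and 2 UMIs in 2 1NMPP1 cells, a log2 ratio of -6.73 (-10.10 to -5.19). Of the other mural markers, Notch3 went from 57 to 0 UMIs, Abcc9 from 50 to 1, Pdgfrb from 25 to 2, Kcnj8 from 17 to 0 and Cspg4 from 12 to 0, while Tagln went from 59 to 67. Within endothelial-like cells that held no UMI of a mural marker the medians were -0.65 for inflammatory, -0.32 for FGF and ERK feedback, 0.46 for immediate early and 0.03 for hypoxia genes, and Il6 was at 0.61, Ccl2 at 1.92 and Ptgs2 at -1.59. There Frmpd4 was at 3.80, Nebl at 1.13, Phlda1 at -0.51 and Adm at -0.18. Hmox1 was at -2.13, Stc1 at -2.03 and Ccdc86 at -1.66, and Zbtb16, a target of glucocorticoid signalling, was at 2.57, Nebl at 2.56 and Frmpd4 at 2.28. The inflammatory median was -0.39 (6 of 10 members lower, percentile 0.12), with Il6 at -2.37, Ccl2 at -2.04 and Ptgs2 at 2.25, and Ptgs2 was at -0.50 within male-called cells. FGF and ERK feedback genes had a median of -0.34 (9 of 12 members lower, percentile 0.32), with Dusp4 at -1.58 and Phlda1 at -1.20, and hypoxia and glycolysis genes of -0.19 (percentile 0.78), with Pgk1 at -0.75 and Adm at -0.97. After thinning the inflammatory median was 0.29 and the FGF and ERK feedback median 0.16, from only 5 and 6 measured members. Immediate early genes had a median of 0.47 (percentile 100), with Zfp36 at 0.90 and Fos at 0.76. The angiogenesis (0.18, with Kdr at 0.22 and Flt1 at 0.11, or -0.10 under median-of-ratios scaling), interferon (0.25), proliferation (0.23), neurotrophin (0.30) and antigen presentation (0.21) medians lay within the central 95%, and the median of all genes was 0.23.

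DRG fibroblast-like cells, 122 and 117 cells, had higher axon guidance genes and lower interferon genes. Neurotrophins and axon guidance genes had a median of 0.53 (7 of 9 members higher, percentile 99.7), with the guidance ligands Ntn1 at 1.22 (0.99 to 1.45), Sema3d at 0.73 and Slit3 at -0.73. The interferon median was -0.47 (8 of 12 members lower, percentile 0.11), with Ifit1 at -2.28, Ifit3 at -1.46 and Oasl2 at 1.05. The immediate early median was 0.33, with Btg2 at 1.08 and Zfp36 at 1.04, and the angiogenesis median -0.33 (8 of 9 members lower, percentile 1.23), with Esm1 at -1.47 and Vegfc at -0.92. Fibrous matrix (0.16, with Col1a1 at -0.13), BMP and TGF-beta (0.20), FGF feedback (0.18), inflammatory (0.11), proliferation (0.0052) and hypoxia (0.18) medians lay within the central 95%. The genes named were Lypd2 at 2.71, Igf2 at 2.48 and Dio2 at 2.32, and Dnah12 at -3.86, the chemokine Cxcl12 at -3.13 and Fat3 at -1.68, of which Igf2 shares its transcript end with an overlapping gene model and is uncertain. After thinning Vegfc, Esm1 and Oasl2 were at 0.75, 0.10 and -0.26, and the median of all genes was 0.11.

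DRG macrophage-like cells, 68 and 60 cells read after the data were seen, had higher immediate early genes (median 0.79, 15 of 16 members), with Egr1 at 1.28 and Dusp1 at 1.15. Their inflammatory median was 0.35 (percentile 99.7), with Il1b at 1.07, and their FGF and ERK feedback median 0.63, with Dusp6 at 1.33. The genes named were C4b at 2.84, which shares 39.1% of its transcript end with C4a, Wfdc17 at 2.36 and Ccl8 at 2.07, and Gdf15 at -2.12, the peroxiredoxin Prdx1 at -1.63 and Specc1 at -1.61. Antigen presentation genes had a median of 0.30 (percentile 99.0). Of the 3 clusters of this class, 1 held 24 vehicle and 26 1NMPP1 cells, 1 held 26 and 13, and the shallowest, with a median of 1377 UMIs, held 18 and 21. The alternatively activated (0.03), interferon (0.08), proliferation (-0.07) and hypoxia (0.16) medians lay within the central 95%.

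Interferon response genes were also higher in the neutrophil-, B cell- and monocyte-like cells of the 1NMPP1 DRG library. It was not tested whether these cells came from the ganglia or from tissue carried along. In neutrophil-like cells 14 of 14 members were higher (median 1.08, percentile 100), with Usp18 at 2.17 (1.15 to 3.47), Irf7 at 1.61, Xaf1 at 1.32 and Ifit3 at 1.13. In B cell-like cells 13 of 13 were higher (median 1.64), with Usp18 at 2.59, Irf7 at 2.41 and Isg15 at 1.66, and the median was 0.74 within their largest cluster alone, with Irf7 at 1.23. The list was also higher in monocyte-like cells, 63 and 89 cells read after the data were seen, in 12 of 12 members (median 1.18). Ifit3 in neutrophil-like cells turned to -0.31 within female-called cells.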

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

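The values in this part are given as measured and no difference between tissues was tested, while the comparison with blood cells, the thinning of lists and the reading of a largest cluster were chosen after the results were seen. Signal was seen outside the comparisons, in the sequences added to the feature tables. The vehicle growth plate library held 95 UMIs of AAV_PHP_S in 9 barcodes, of which 84 UMIs lay in 3 endothelial-like cells and 3 in 1 barcode that was not kept, and the sequence is not among the features counted in the 1NMPP1 growth plate library. The vehicle DRG library held 857 UMIs of tdTomato in 195 barcodes, with 643 in 51 of 402 sensory neuron-like cells (12.7%, median depth 1041.5 UMIs). Blood cells give the background, with a UMI in 18 of 341 neutrophil-like (5.28%, median depth 8378 UMIs) and 11 of 300 B cell-like cells (3.67%). The share of satellite glia-like cells with a UMI was within that range, at 23 of 592 (3.89%). Their 48 UMIs lay unevenly, with 12 in 1 cell, whereas neutrophil-like cells held at most 1 and B cell-like cells at most 2. Fibroblast-like cells there held 32 UMIs in 8 of 122 cells. The 1NMPP1 DRG library held 1740 UMIs of tdTomato in 68 barcodes, with 1558 in 17 of 115 sensory neuron-like cells (14.8%, median depth 19716 UMIs), 803 of them in 1 cell, and 135 in 11 of 117 fibroblast-like cells. Its background was 6 of 470 neutrophil-like (1.28%) and 3 of 294 B cell-like cells (1.02%), and 0 of 184 satellite glia-like cells held a UMI, which allows a share of up to 1.98%.

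The other values stand here because the log2 ratio of 1NMPP1 over vehicle pointed one way in the growth plate and the other way in the DRG. For proliferation genes in B cell-like cells the median was 0.16 in the growth plate and -0.73 in the DRG. For inflammatory genes it was 0.0692 and -0.46 in monocyte-like cells, and -0.40 and 0.35 in macrophage-like cells. After thinning to 1000 UMIs both monocyte-like medians took the other sign, at -0.063 and 0.39, and within the largest growth plate cluster the median was -0.0616. For immediate early and dissociation stress genes in macrophage-like cells it was -0.37 and 0.79. The share of erythroid-like cells had a log2 ratio of -0.48 in the growth plate and 0.85 in the DRG. With 1 library per group and tissue, none of these differences was tested.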

How the results depend on the processing

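The settings male-called cells, female-called cells, thinning for lists, peptidergic-like clusters, the largest cluster of a class (DRG satellite glia-, Schwann- and B cell-like, growth plate neutrophil- and monocyte-like) and endothelial-like cells without mural marker UMIs, and all settings for classes from 30 cells (growth plate chondrocyte-, macrophage-, mast- and megakaryocyte-like, DRG macrophage- and monocyte-like), were chosen after the results were seen. No paired analysis was possible because each group has 1 library. Of 248 share ratios under alternatives, 204 stayed within the counting interval, 38 moved outside it and 6, with an interval that had left out 0, took the other sign. Of 822 list medians, set against the width of their random lists, these were 626, 165 and 31, and of 2091 gene ratios 1513, 495 and 83. Settings that left under 10 cells of a class in a library gave no expression values. At resolutions of 0.5 and 2 all 30 shares stayed within their intervals. Chondrocyte-like cells were 39 in the 1NMPP1 library, and sensory neuron-like cells had median depths of 1041.5 and 19716 UMIs. The values that turned sign, and the values of the main shares and lists that moved, follow as log2 ratios by setting, and the cause was not tested. With named genes from 30 UMIs, 22 of the 36 names stayed. From 500 genes, growth plate neutrophil-like Mmp8 was at 0.0267, chondrocyte-like Col1a1 at 0.26 and the DRG neuron share at -1.07 (255 and 93 cells). Up to 10% mitochondrial UMIs, Mmp8 was at 0.0069, chondrocyte-like Col2a1 at -0.0007 and DRG fibroblast-like Col1a1 at 0.25. Thinned to 1000 UMIs, growth plate interferon medians were 0.16 in B cell-like and 0.38 in monocyte-like cells, dendritic-like proliferation 0.0305 and immediate early -0.0189, and monocyte-like inflammatory -0.063 and proliferation -0.035. Thinned DRG medians were 0.16 for FGF and ERK feedback and 0.29 for inflammatory genes in endothelial-like cells, 0.36 for inflammatory and 0.28 for proliferation genes in satellite glia-like cells, 0.21 for axon injury, 0.044 for general nociceptor and -0.48 for non-peptidergic genes in neurons, and 0.39 for monocyte-like inflammatory genes. The endothelial-like medians rested on 6 and 5 members and the satellite glia-like ones on 4 each. Thinned genes were granulocyte progenitor-like Hspa1b (0.0346), chondrocyte-like Fam155a (-2.15), growth plate macrophage-like Cd163 (-0.26), DRG B cell-like Ciita (-0.091), endothelial-like Adm (0.17), fibroblast-like Oasl2 (-0.26), Esm1 (0.10) and Vegfc (0.75), Schwann-like Mbp (-0.10), macrophage-like Specc1 (0.0698), and in neurons Slamf1 (-1.31), Kcnmb2 (0.40), Bdnf (0.0769), Scn11a (-0.43), Kcnc1 (0.85), Gap43 (0.21) and Gal (1.18). With each library clustered on its own, the chondrocyte-like share was at -1.08 (68 and 39 cells), the growth plate neutrophil-like share at 0.37, the DRG monocyte-like share at -0.41 and the DRG granulocyte progenitor-like share at 6.63, the last from 0 and 37 cells and so set by the added 0.5. Among cells that are not blood, shares were at -0.72 for chondrocyte-like, -0.66 for satellite glia-like and -0.78 for sensory neuron-like cells. As a list mean, B cell-like interferon was 0.64. From 100 UMIs per member, monocyte-like interferon was 0.46 and chondrocyte-like proliferation -0.0938. Under median-of-ratios scaling, endothelial-like Flt1 was at -0.10. With cells weighed alike, Cd163 was at -1.46, Mbp at -0.31, and in neurons Slamf1 at -1.71, Kcnmb2 at 0.34, Ndst4 at 0.21, Calca at 0.19, Trpv1 at 0.355, Scn11a at -0.14, Kcnc1 at 0.12, Runx3 at 0.0807, Gap43 at 0.84, Gal at 1.30 and Sprr1a at 0.27. With no doublet removal, chondrocyte-like Col2a1 was at -0.0456, Acan at -0.054, Col1a1 at 0.38, Col1a2 at 0.21, Tnc at 0.29, Ibsp at 0.93, Spp1 at 3.54, Fgfr1 at 0.19, Etv5 at 0.38, Kitl at 1.27 and Vcam1 at 0.86, and neuronal Mrgprd at 0.27. In peptidergic-like clusters, axon injury was at 0.12, general nociceptor at 0.0332, A-fibre at 0.31, Gfra2 at -1.05, Nefh at 0.51, Atf3 at 0.14, Gap43 at 0.0754 and Gal at 0.16. In the largest cluster alone, growth plate neutrophil-like medians were 0.47 for interferon, -0.0452 for inflammatory and 0.33 for proliferation genes, with Isg15 at -0.18, and monocyte-like medians 0.27 for interferon, -0.0616 for inflammatory and -0.0082 for immediate early genes, with Cxcl1 at -0.78 and Il1a at -0.11. In DRG endothelial-like cells without mural marker UMIs, hypoxia was at 0.0322, Ccl2 at 1.92, Il6 at 0.61 and Ptgs2 at -1.59. In the largest cluster of their classes, DRG B cell-like medians were 0.74 for interferon, 0.22 for antigen presentation and -1.39 for proliferation, and satellite glia-like medians 0.71 for immediate early and 0.38 for cholesterol synthesis genes. In female-called growth plate cells, the neutrophil-like share was at 0.31, interferon at -0.12 in B cell-like (Ifit1 -0.0578, Ifit3 -0.17), 0.71 in monocyte-like and 0.44 in neutrophil-like cells, progenitor-like immediate early at 0.0518, proliferation at -0.24 in monocyte-like, 0.20 in neutrophil-like, -0.10 in chondrocyte-like and 0.048 in mast-like cells, Mmp8 at 0.0449 and Col10a1 at -0.84. In female-called DRG cells, the neuron share was at 0.14 (15 and 30 cells), endothelial-like Flt1 at -0.0637, fibroblast-like Col1a1 at 0.35 and Vegfc at 0.18, Schwann-like immediate early at 0.52 and Dhcr7 at -0.03, neutrophil-like Ifit3 at -0.31, satellite glia-like proliferation at 0.73, immediate early at 0.51, Top2a at 2.75 and Ube2c at 1.96, and in neurons axon injury at -0.86, A-fibre at 0.93, Nefh at 2.43 and Sprr1a at 3.19. In male-called growth plate cells, shares were at -2.57 for chondrocyte-like (82 and 8 cells) and 0.0175 for neutrophil-like cells, interferon at 1.09 in B cell-like, 0.77 in monocyte-like and 1.13 in neutrophil-like cells, B cell-like antigen presentation at -0.0464, NK-like proliferation at 0.60, Ccnb1 at 1.10 and Mki67 at 0.57, progenitor-like Hspa1b at 0.12 and Mmp8 at 0.0923. In male-called DRG cells, shares were at -0.0313 for B cell-like, 0.0414 for mural-like, -1.03 for satellite glia-like and 0.39 for neurons, endothelial-like Ptgs2 at -0.50 and Adm at 0.0528, fibroblast-like Col1a1 at 0.0427, immediate early at 0.94 in Schwann-like and 1.22 in satellite glia-like cells, monocyte-like alternatively activated genes at 0.0671, and in neurons axon injury at 0.14, general nociceptor at 0.0439, Adamts13 at -1.54, Trpv1 at 0.27, Atf3 at 0.35 and Gal at 0.70.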

Other observations

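The tests of interferon genes in erythroid-like cells and of Col1a1 in neutrophil-like cells were set before their results were seen, and all other tests in this part were chosen afterwards. B cell-like cells of the 1NMPP1 DRG library had higher antigen presentation genes and lower proliferation genes. All 12 members of the antigen presentation list were higher, with a median of 0.93 (percentile 100), among them H2-DMb1 at 1.56 and the class II regulator Ciita at 1.26, or -0.09 after thinning. Of 18 proliferation genes 16 were lower (median -0.73, percentile 0), with Ccnb1 at -1.62 and Top2a at -0.99, and immediate early genes had a median of 0.67 (13 of 16 members higher). The class took different parts from the libraries, with 71 of 300 vehicle and 136 of 294 1NMPP1 cells in a cluster led by Igkc, Cd79a and Ms4a1, and 54 and 3 in another. Within the former alone, a test chosen after the data were seen, the antigen presentation median was 0.22, the immediate early median 0.24 and the proliferation median -1.39. There H2-DMb1 was at 0.61, Ciita at 0.54 and Top2a at -3.20. In growth plate B cell-like cells proliferation (0.16, 16 of 18 members), immediate early (0.21, 13 of 16 members, with Hspa1a at 1.70) and antigen presentation genes (0.13, 10 of 12 members) were higher and the hypoxia median was 0.03. The antigen presentation median turned to -0.0464 within male-called cells there. Proliferation genes were lower in growth plate dendritic-like cells (median -0.21, 15 of 18 members, percentile 0.05, with Top2a at -0.69 and Mki67 at -0.64) and NK or innate lymphoid-like cells (median -0.26, 16 of 18 members, percentile 0.11, with Ccnb1 at -1.45 and Mki67 at -0.61), and thinning took the dendritic-like median to 0.03. Within male-called NK or innate lymphoid-like cells the median turned to 0.60, Ccnb1 to 1.10 and Mki67 to 0.57. They were also lower in 73 and 64 mast or basophil-like cells (median -0.32, 14 of 18 members, percentile 0.20), a class read after the data were seen, and the median turned to 0.048 within female-called cells. That class has 2 clusters, with 33 and 41 cells in the former and 40 and 23 in the latter, where granulocyte progenitor markers scored next. In 72 and 70 megakaryocyte or platelet-like cells, also read after the data were seen, the proliferation (0.0659), immediate early (0.13) and hypoxia (0.0054) medians lay within the central 95% of random lists.

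Glycolytic genes were lower in DRG erythroid-like cells of the 1NMPP1 library. All 10 measured members of the hypoxia and glycolysis list were lower, with a median of -1.87 (percentile 0) against a median of -0.44 over all genes of this class, and Ldha was at -2.91 (-3.41 to -2.48), Pgk1 at -1.92 and Pkm at -1.87 from 34 and 8 UMIs. In growth plate erythroid-like cells the same list had a median of -0.45 (percentile 11.6). In DRG monocyte-like cells, 63 and 89 cells read after the data were seen, 12 of 16 inflammatory genes were lower (median -0.46, percentile 0), 4 of 6 alternatively activated macrophage genes were lower (median -0.52) and immediate early genes had a median of 0.32 (percentile 100). The inflammatory median turned to 0.39 after thinning, and the alternatively activated median to 0.0671 within male-called cells. In DRG neutrophil-like cells the inflammatory median was -0.13 (percentile 2.59), the granule median 0.08 and the immediate early median 0.05. A DRG cluster of 54 cells, all from the vehicle library (1.90% of its kept cells), was led by Col2a1, Ibsp, Chad, Snorc, Prg4 and Acan and stayed without a name, since chondrocyte markers had been fixed for the growth plate alone. The 1NMPP1 DRG library had 0 such cells of 2151, which allows a share of up to 0.139% if a count of 0 is taken to allow 3 cells.

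Interferon response genes were higher in growth plate neutrophil-like cells of the 1NMPP1 library, and 0 of the 14 members shared sequence with another gene. Free RNA was tested first in erythroid-like cells, where the summed CPM of the list went from 545 to 895. This difference is 156.5% of that in neutrophil-like cells (358 to 582), which met the mark set beforehand for free RNA. Since it exceeds the neutrophil-like difference, the test cannot tell free RNA from transcripts of the erythroid-like cells themselves. A later test in B cell-like cells, with UMIs of the list per cell going from 1.42 to 2.23 there and from 2.63 to 4.49 in neutrophil-like cells, gave 43.5% with an upper counting bound of 49.7%, which argues against free RNA as the whole cause and leaves it open as a part. A different mix of male and female cells is argued against, since the mix alone would give a median of -0.0877 (-0.21 to 0.03 over resampled cells) with the levels of the vehicle library and of -0.33 (-0.40 to -0.23) with those of the 1NMPP1 library, and the list was higher within male-called (1.13, 0.92 to 1.33) and within female-called cells (0.44, 0.11 to 0.74). Other differences between the pooled animals (within the 1NMPP1 library the list's median was -0.86 in female-called over male-called cells) and a response to the compound or the blocked receptor (1.08 in DRG neutrophil-like cells) cannot be told apart with 1 library per group.

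In the growth plate 25 genes, such as Hist1h2ap, Rpl35 and Eno1 among 11 that were higher and Gm2000 and Rpl10-ps3 among 14 that were lower, differed the same way in every class where they were measured. Reads shared between near-identical copies are a candidate explanation, since 76.0% of these genes (19 of 25) share sequence with another gene, against 3.97% of the 7400 genes compared and at most 24% in 1000 random sets. A different mix of male and female cells is argued against by a median size of 1.20 within male-called and 1.24 within female-called cells, against 1.25 over all cells. A response to the compound that is alike in both tissues is argued against by a median of 0.22 over DRG classes, for the 24 genes measured there, against 1.22 in the growth plate. The genes were picked by their growth plate values. A response in the growth plate alone therefore cannot be told apart with 1 library per group. What sets these genes apart in these libraries stays open, since some that share no stretch with another gene differed too, such as Ahsa1 (1.24), Sap18 (1.22) and Ddah1 (-1.01). For some genes the vehicle growth plate library stood apart from all others. Eno1 was at 31.7 CPM there, against 141 in the 1NMPP1 growth plate, 158 in the vehicle DRG and 139 in the 1NMPP1 DRG library. Rpl35 was at 165 against 764, 731 and 705 CPM in that order, and Gm2000 at 230 against 119, 107 and 142 CPM. Others did not follow this, such as Hmgn2 at 229 against 545, 167 and 205 CPM, and the tissues differ in their cells. The feature tables of the growth plate libraries differ by AAV_PHP_S where those of the DRG libraries are alike.

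Fibrous matrix genes were lower in chondrocyte-like cells of the 1NMPP1 library, with a median of -0.43, which was again -0.43 without the 5 vehicle cells holding 68.2% of the vehicle Col1a1 UMIs of this class and was -0.75 within the cluster of this class led by Prg4 and Chad. Col1a1 itself moved to -4.84 without those 5 cells, and 45 vehicle and 9 1NMPP1 cells of the class held a UMI of it. Free RNA in the vehicle library is argued against by a log2 ratio of Col1a1 of 0.19 (-0.01 to 0.40, from 322 and 499 UMIs) in neutrophil-like cells, against -6.39 in chondrocyte-like cells. The border between chondrocyte-like and fibroblast-like clusters stays open, since the median was -0.14 from 500 genes and -0.15 at resolution 2, where 4 and 5 fibroblast-like cells of the 1NMPP1 library joined the class and Col1a1 was at 0.26 and 0.31. With each library clustered on its own, where 48 vehicle cells left for fibroblast-like clusters, the median was -0.12, but Col1a1 was at -7.63 and Col3a1 at 5.39. A response to the compound cannot be told apart with 1 library per group, and the median in fibroblast-like cells was -0.0185 (percentile 47.6).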
